A study of Trichoderma atroviride
Rhizoctonia solani and Trichoderma atroviride with 6 samples.

How the data were processed

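RNA of the mycoparasitic fungus Trichoderma atroviride strain P1 was hybridised to a high-density oligonucleotide array of Trichoderma sequences in 6 single-colour (Cy3) hybridisations, 3 of mycelium before contact with the plant pathogen Rhizoctonia solani and 3 of mycelium after contact. Per the labels' protocols, both fungi grew on cellophane over potato dextrose agar at 25 °C for about 24 h. The control was taken with the colonies 5 mm apart and the test mycelium 5 mm after contact. RNA was extracted with TRIzol, cleaned on columns, and sent for labelling as 40 µg per set of 3 arrays. The design text says that each condition was hybridised in triplicate and does not say whether the 3 arrays of a condition came from separate cultures. The p-values therefore measure only the spread between these arrays, which may be technical.

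Of the deposited files, 1 set per array holds unnormalized intensity values, the mean brightness of a feature's probes (5 probes for nearly all features, no mismatch signal), per the file headers. The second set holds intensity values on a linear scale that the authors made with RMA, a method that corrects background, equalises the distributions of the arrays and summarises probes, per the submitters' processing notes and file headers. The version of RMA and the scanner are not given in the sources used here. Each file gives 2 values per feature. They were averaged here on the log2 scale, giving 35682 features. On the 1 array where this was counted, the RMA standard error of 36 values is marked -99. Expression values so marked were kept on every array. The value table of the series was checked against the scanner values: it equals the geometric mean of the 2 unnormalized values of each feature and array (largest gap 1.60e-06 on the log2 scale), so its scale is linear, it is not centred, and it is not normalized between arrays. Its column medians were 212, 1956 and 3745 before contact and 315, 310 and 2269 after contact. No column of another sample was present (0 unused columns).

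The features carry identifiers and no description of function. There are 11098 gene models with T. atroviride identifiers, 11638 with identifiers of the related species T. virens, and 12946 expressed sequence tag (EST) features with 10 source codes such as T34 or TP1, whose meaning is not given in the sources used here. The files tag the T. atroviride identifiers as VIRENS and the T. virens identifiers as ATRO. The identifiers were followed here, since features with T. atroviride identifiers had a median level of 11.89 on the log2 RMA scale and those with T. virens identifiers 5.88. The number in a T. atroviride identifier was matched to the older locus tags of a RefSeq gene table (assembly ASM2064779v1), which gave a current locus tag to 4572 gene models (41.2%). In these, 90.7% lay on the chromosome that held most of the matches of the scaffold named in their model name, against at most 21.3% in 100 shuffles. The table gives no gene functions, and its coordinates were used only to say which loci are neighbours.

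The main test was limma's lmFit and eBayes (limma 3.58.1, R 4.3.3) on log2 of the RMA values, 3 arrays after contact against 3 before, without covariates or a filter on dim features, two-sided, with Benjamini-Hochberg adjustment over all features and an adjusted p threshold of 0.05. A second count required a change of at least 2-fold. Fold changes are after over before. The comparison, the tests, the rule for named features and most alternatives were fixed before the data were examined. The rule for files without annotation names the 2 features with the largest rise and the 2 with the largest fall among those past the threshold whose 3 arrays of one group lie above all 3 of the other. The 19 functional gene lists fixed in advance (chitin and glucan degradation, proteases, transport, secondary metabolism, stress, translation and others) were patterns on annotation text, so 0 of them could be tested here. Feature classes were tested instead as sets with limma's camera at its preset correlation of 0.01, again with an estimated correlation, and with fry, which asks whether the genes of a class move on balance one way. These class tests, the class values under each scaling, the brightness sets and the level bands were chosen after seeing the data.

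Unnormalized array medians ran from 212 to 4092, a 19.3-fold range, with 3 dim arrays (212, 310 and 315) and 3 bright ones (2192, 2376 and 4092). Each set holds both groups: the dim set 2 arrays after and 1 before contact, the bright set 1 after and 2 before. The sets also follow the numbers in the sample titles, which are lower for every dim array than for any bright array. Whether the sets are batches is not stated in the labels. The set was added as a block in an alternative fit, and values within each set are given. The number of arrays limits the precision. The level of a feature is its mean log2 RMA value over the 6 arrays. No detection call was used here. The T. virens features served as a guide to background, and their 5th percentile was subtracted to give net unnormalized intensities. The test was tested on simulated data. In data drawn from the means and spread of these arrays, over 35682 features with 200 changed, the main test recovered 16% of 2-fold and 71% of 4-fold changes, with 2 of the unchanged features called. The simulated noise was independent between features, and far fewer features changed than passed in the real data. These rates therefore need not hold for the real arrays. Alternatives covered the normalization, the series value table, centring, filters on dim features, the test, the threshold, and each array left out. Averaging features with the same annotation text was not run, because there is none. Shuffles of neighbouring loci used Python 3.11.15 and numpy 2.4.6.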

Results

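Transcript levels of Trichoderma atroviride P1, a soil fungus that attacks other fungi, were measured before and after its mycelium met a colony of Rhizoctonia solani, with 3 arrays per condition. The question posed by the design is which transcripts change during the mycoparasitic interaction. The groups are earlier and later stages of the confrontation, and no sample was grown without R. solani. An effect of contact therefore cannot be told apart from other differences between these stages. Each array held 35682 features: 11098 gene models of T. atroviride, 11638 of T. virens and 12946 EST features with 10 source codes. The T. atroviride gene models were the brightest gene model class, with 73.7% of them above 9 on the log2 RMA scale, against 12.8% of the T. virens gene models. Among EST features the code TP1, which contains the strain name P1, had 85.0% above that level, T53 55.4%, T11 54.4%, and the remaining 7 codes between 16.6% and 32.4%. Features were named only by identifier, and no function is attached to any of them.

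The arrays grouped by condition. Correlations over features were 0.989 to 0.994 between arrays of one condition and 0.952 to 0.966 between conditions, and the first principal component, which separated the conditions, held 73.5% of the variance. Correlations over features describe these arrays and are not a test, since features are not independent replicates. No pair of arrays held identical values. The duplicate values of a feature on one array differed with an SD of 0.137 to 0.186 (log2, unnormalized) on the dim arrays and 0.376 to 0.600 on the bright ones. In the RMA values, on which the main test ran, this SD was larger, 0.442 to 0.478 on the dim arrays and 0.596 to 0.721 on the bright ones. On the bright arrays 2.27% to 9.35% of features exceeded an intensity of 60000, near the top of the scale, against at most 0.00841% on the dim ones.

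After contact, 5283 features were higher and 4269 lower (limma, Benjamini-Hochberg adjusted p below 0.05), and 26130 did not pass. Of those that passed, 3793 rose and 2130 fell at least 2-fold, 5923 in all. That total was 3223 with the unnormalized values quantile-normalized, 4510 with them median-centred, and 6735 once every array was shifted to one median. Large rises outnumbered large falls: 1230 features rose and 196 fell at least 4-fold, 398 rose and 18 fell at least 8-fold, and 175 rose and 2 fell at least 16-fold. The 3 arrays of one condition lay entirely above the 3 of the other in 14590 features (40.9%), where chance gives 10%. The balance of the calls depended on the scaling: 55.3% of the calls were rises with the RMA values as deposited, 36.3% once every array was shifted to one median (which moved the median of all features by -0.227), and 48.0% and 36.5% when the unnormalized values were quantile-normalized or median-centred.

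T. atroviride gene models accounted for most rises. Of the 11098, 4008 (36.1%) were higher and 1838 (16.6%) lower after contact, and 5252 did not pass. At least 2-fold, 2979 rose and 810 fell, and at least 16-fold, 118 rose and 2 fell. Relative to the other features they shifted upward as a set (camera adjusted p = 3.63e-08), a call that was lost with an estimated correlation between genes (adjusted p = 0.419 with an estimated correlation). Tested against no change instead of against other features, they moved upward on balance in the RMA values (fry adjusted p = 0.0215). Their median log2 fold change was 0.19 and turned to -0.04 once every array was shifted to one median and to -0.03 with the unnormalized values median-centred, where 2165 were higher and 2092 lower. Among the gene models with a mean level of at least 10, 1392 were higher and 1673 lower, out of 7372, while at least 2-fold 824 rose and 707 fell. With the unnormalized values median-centred, 587 of them were higher and 1882 lower.

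**Figure D1:**
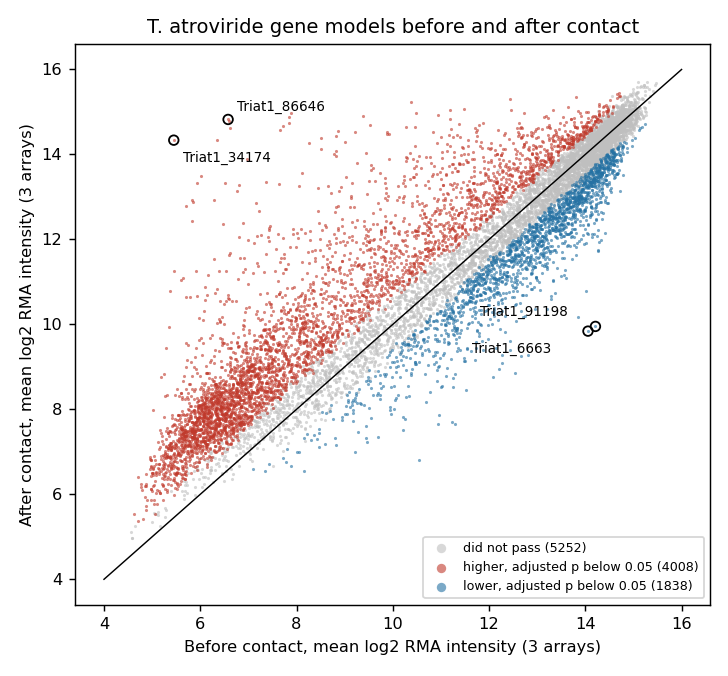
Mean log2 RMA intensity of each T. atroviride gene model before (x axis) and after contact (y axis), over 3 arrays each; red and blue points passed an adjusted p of 0.05 (4008 higher, 1838 lower), grey points did not, and the line marks equal levels. The 4 circled features are those with the largest rises and falls in these values; at the dim end nearly the whole cloud lies above the line.

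The largest rise in the RMA values was that of Triat1_34174, a gene model on scaffold 2 of the T. atroviride assembly that the array was designed on, matched to locus TrAtP1_002523. Its log2 RMA level was 5.45 ± 0.21 (SD, n = 3) before and 14.34 ± 0.10 (SD, n = 3) after contact, a log2 fold change of 8.89 (SE 0.16, limma adjusted p = 7.27e-07). The next was Triat1_86646 on the same scaffold, matched to TrAtP1_002524, the adjacent locus. It went from 6.58 ± 0.08 to 14.82 ± 0.08 (SD, n = 3), a log2 fold change of 8.25 (SE 0.13, limma adjusted p = 7.19e-07). Both began at levels found among T. virens features, at their 35.8th and 62.9th percentiles. The sizes and the order of these rises depended on the processing, in which background treatment was not varied alone. Their log2 changes were 5.72 and 5.80 with the unnormalized values quantile-normalized, where Triat1_86646 rose more.

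The largest falls in the RMA values were those of Triat1_91198 on scaffold 10 and Triat1_6663 on scaffold 4, neither matched to a current locus tag. Triat1_91198 dropped from 14.21 ± 0.15 to 9.95 ± 0.30 (SD, n = 3), a log2 fold change of -4.26 (SE 0.19, limma adjusted p = 1.11e-05). Triat1_6663 dropped from 14.06 ± 0.12 to 9.84 ± 0.15 (SD, n = 3), a log2 fold change of -4.21 (SE 0.15, limma adjusted p = 4.15e-06). With the unnormalized values quantile-normalized they were -2.53 and -3.93, where Triat1_6663 fell more. Within the dim and the bright arrays taken separately, log2 changes were 9.07 and 8.88 for Triat1_34174 and 8.22 and 8.19 for Triat1_86646. They were -4.26 and -4.25 for Triat1_91198, and -4.04 and -4.40 for Triat1_6663. The direction within each set was fixed in advance, since features were named only where the arrays of the groups did not overlap.

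The change of a T. atroviride gene model depended on its level. Of the 2003 gene models at a mean level of 5 to 8, 1674 (83.6%) were higher and 19 lower (910 and 32 with the unnormalized values median-centred), 96.0% had a positive fold change, and the median log2 fold change was 1.36 (SD of the median over the 3 after-contact arrays 0.04). Of the 1719 at 8 to 10, 942 were higher and 146 lower, with a median of 0.84, against 0.49 with the unnormalized values quantile-normalized and 0.40 with them median-centred. From a level of 10 upward the median was -0.05, against -0.30 with the unnormalized values median-centred and -0.28 once every array was shifted to one median. Among T. virens gene models of level 5 to 8, 88 of 7159 were higher and 522 lower, and the median was -0.14. It was 0.02 with the unnormalized values median-centred and -0.36 once every array was shifted to one median, where 50 were higher and 1345 lower. With the unnormalized values quantile-normalized, 169 of these T. virens gene models were higher and 762 lower. The rise at low level stood in both brightness sets, with medians of 1.37 in the dim and 1.34 in the bright arrays, and the median was 0.56 with the unnormalized values quantile-normalized, 0.64 with them median-centred and -0.29 in the series value table, which is not normalized. The level trend was also removed within each class, a setting chosen after seeing the data. At an adjusted p below 0.05, 2360 T. atroviride gene models then lay above and 2012 below the trend. Of these, 1421 and 986 did so by at least 2-fold. Removal centres each class on its trend, so this setting does not test the balance of rises and falls.

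**Figure D2:**
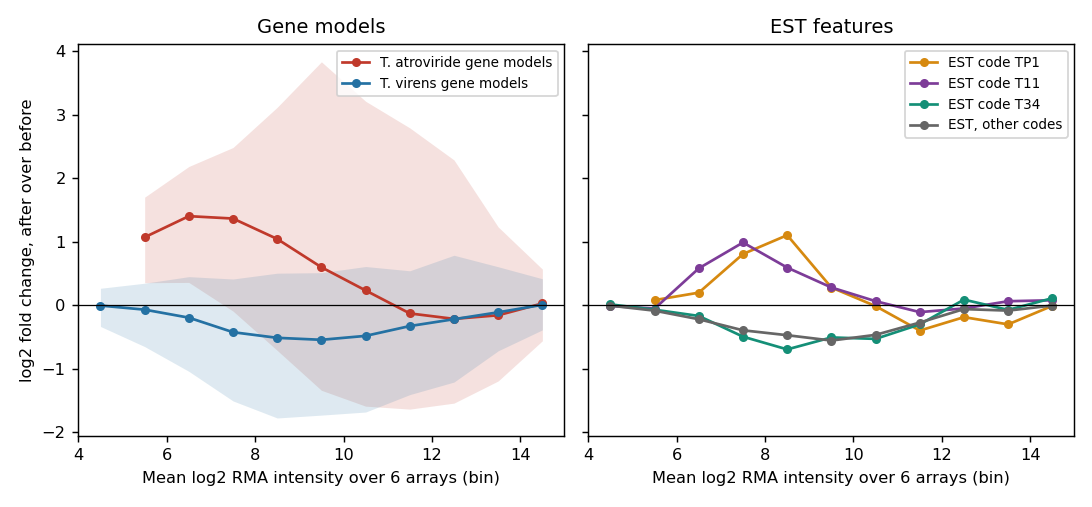
Median log2 fold change (after over before contact) of features binned by their mean log2 RMA intensity over the 6 arrays, for gene models (left, with shaded 5th to 95th percentiles) and for EST features by source code (right; bins of under 20 features are left out). T. atroviride gene models peak at a median of 1.40 in the bin from 6 to 7, and TP1 and T11 features have medians above 0 in the bins from 6 to 9, while the medians of T. virens, T34 and the 7 other codes lie below 0 in the bins from 5 to 12.

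The dimmest T. atroviride gene models showed the same in the unnormalized values. Their 5th percentile, net of the T. virens 5th percentile, was 24.5 on the dim array before contact and 84.0 and 90.5 on the dim arrays after contact. On the bright arrays it was 268 and 458 before contact and 741 after. On the log2 RMA scale the 10th percentile of the class was 6.32 to 6.56 before and 7.75 to 7.87 after contact, while that of the T. virens gene models stayed between 4.72 and 4.77 on all 6 arrays. RMA equalises the distributions of the arrays, so this steadiness at the dim end may come from the normalization.

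**Figure D3:**
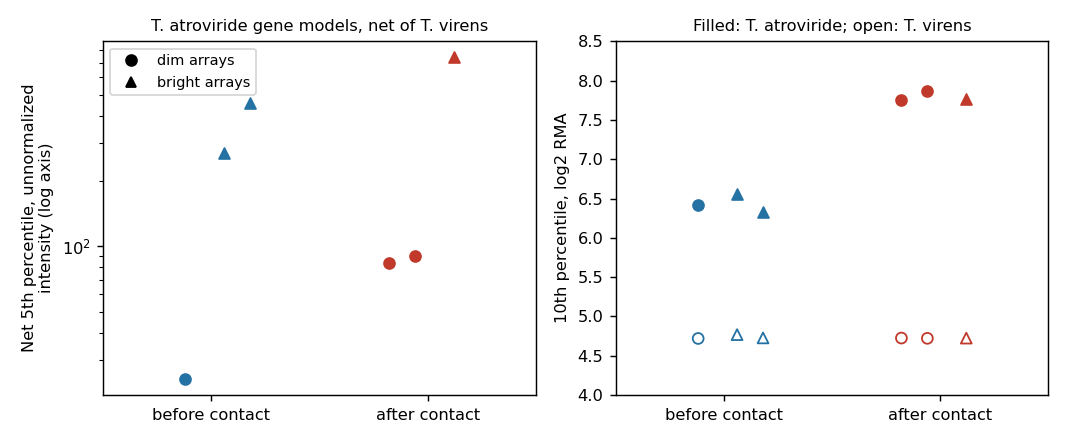
Low end of the intensity distribution on each of the 6 arrays. Left, 5th percentile of the T. atroviride gene models minus that of the T. virens gene models, unnormalized intensity on a log axis; right, 10th percentile of each class in log2 RMA values, where the T. atroviride points after contact (7.75 to 7.87) lie above all those before contact (6.32 to 6.56).

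Most calls among T. virens gene models went the other way. No sample was of T. virens, so these features report background or RNA of other species binding to their probes. Their calls are not expression changes of T. virens genes. Of the 11638, 159 (1.37%) were higher and 1053 (9.05%) lower after contact, 65 and 593 of them at least 2-fold, and relative to the other features they shifted downward as a set (camera adjusted p = 0.00039), a call that was lost with an estimated correlation (adjusted p = 0.263 with an estimated correlation). T. atroviride gene models are among the features that camera compares this class with, so the camera results of the classes are not independent. Against no change, T. virens gene models moved downward on balance in the RMA values (fry adjusted p = 0.0287). Their median log2 fold change was -0.12, or -0.01 with the unnormalized values median-centred and -0.35 once every array was shifted to one median. The number lower was 2315 after that shift and 420, beside 352 higher, with the level trend removed. Removing the trend within a class centres that class, so the latter balance follows from the setting and does not test the downward shift. In the RMA values the median was -0.55 at a mean level of 9 to 10 and -0.11 at 13 to 14, while the net unnormalized intensities of the dim arrays gave -0.40 and -0.41 in bands of the same bounds, set by the bright arrays before contact. The number lower was 640 without after-contact array 3 and 693 without after-contact array 2, and the number higher was 95 without after-contact array 1 and 97 without array 3.

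EST features divided by source code. T11 had 546 of 1951 features higher and 214 lower, and its set shift upward (camera adjusted p = 0.00256, mean log2 fold change 0.31) was lost with an estimated correlation (adjusted p = 0.266 with an estimated correlation). Against no change, T11 moved upward on balance (fry adjusted p = 0.00133). The balance of T11 turned with the unnormalized values median-centred, where 278 were higher and 332 lower. Its median of 0.09 became -0.13 once every array was shifted to one median. TP1 had 272 of 1424 higher and 267 lower, a set shift that did not pass (camera adjusted p = 0.771), and 22 features that rose at least 16-fold. Falls outnumbered rises in TP1 with the unnormalized values quantile-normalized (267 higher, 372 lower) or median-centred (155 and 279), and once every array was shifted to one median (225 and 419). In the other 8 codes falls outnumbered rises. T34 had 120 of 3351 higher and 325 lower, T53 87 and 181 of 1247, TST 10 and 82 of 775, and T3K 11 and 82 of 740. Once every array was shifted to one median, these counts were 67 and 680 for T34, 71 and 331 for T53, 5 and 175 for TST, and 5 and 175 for T3K. With the unnormalized values quantile-normalized, T53 had 152 higher and 234 lower, T34 190 and 432, TST 25 and 97, and T3K 19 and 116. Camera gave downward shifts for T34, T3K, TH2 and TST (adjusted p = 0.0403, 0.0103, 0.0469 and 0.0148), none of which held with an estimated correlation (adjusted p = 0.438, 0.419, 0.497 and 0.441 with an estimated correlation). Tested against no change, none of these codes passed (fry adjusted p = 0.0919, 0.057, 0.105 and 0.0815). Below a mean level of 10, the median change was 0.40 for TP1 and 0.19 for T11 features (0.17 and -0.04 once every array was shifted to one median), and 116 of 275 and 374 of 1026 were higher. With the unnormalized values median-centred, 79 and 208 were higher.

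**Figure D4:**
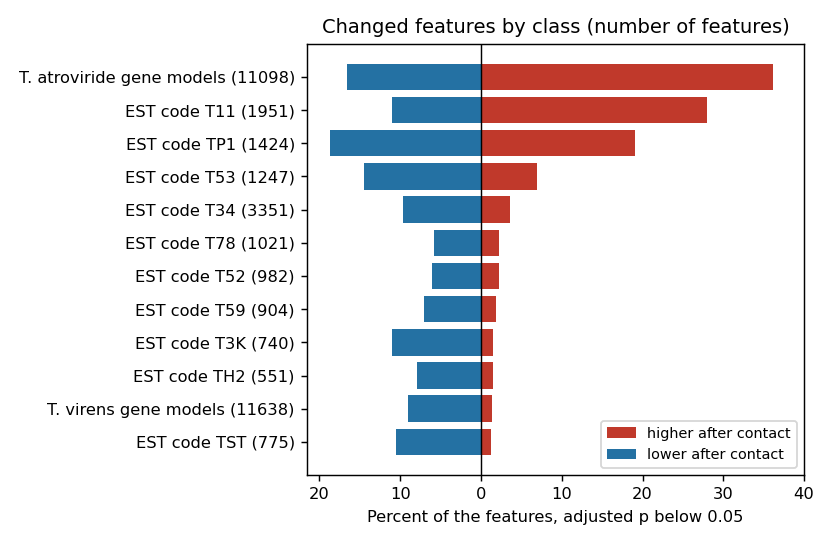
Percent of the features of each class that were higher (red, to the right) or lower (blue, to the left) after contact at a limma adjusted p below 0.05; the number of features is in parentheses. Rises reach 36.1% in T. atroviride gene models, 546 of 1951 features in T11 and 19.1% in TP1, against 1.37% in T. virens gene models.

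With the brightness set as a block, 9162 features changed, 8584 of them shared with the 9552 of the fit without it, and the T. atroviride gene models gave 3828 higher and 1661 lower. Changes within the dim and within the bright arrays correlated over T. atroviride gene models with r = 0.964, a correlation across genes, which are not independent replicates.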

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

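The fits with the brightness set as a block, with a mean level of at least 10, with the level trend removed, and with T. atroviride gene models alone were chosen after seeing the data. No paired analysis was possible because the labels carry no replicate numbers. Over all alternatives, 123 counts stayed within 1.5 times the value reported and 39 did not; the former include all under array weights, trend and robust moderation, and the brightness block on RMA values. The series value table, used as deposited and so not normalized, gave 0 calls by limma in every class (224 features at an unadjusted p below 0.05), log2 changes of 4.68, 5.06, -3.82 and -4.99 for the 4 named features, and a median of -0.29 in place of 1.36 for T. atroviride gene models of level 5 to 8; brightness differences between arrays stay in these values. In the other alternatives run, the 4 named features kept their direction and stayed past the threshold; Triat1_34174 could not enter the fit restricted to a level of 10. Quantile-normalized unnormalized values gave 3223 features changed at least 2-fold and 317 T. virens gene models higher; with the block, 3086, 320 and 1586 T. virens lower. Median-centred unnormalized values gave 2958 features higher and 2165 T. atroviride gene models higher. RMA values shifted to one median gave 7713 features lower, and 94 T. virens gene models higher and 2315 lower. Without features below the median level 96 T. virens gene models were higher, and the plain test left 486 lower. At an adjusted p below 0.01 there were 6367 features changed, 2260 lower, 1143 T. atroviride gene models lower, and 63 T. virens higher and 425 lower. At a level of at least 10, where fewer features are tested, 5390 changed, 2304 of them 2-fold, with 2220 higher, 1611 T. atroviride higher, and 55 T. virens higher and 285 lower. With the level trend removed, which centres each class, there were 3910 2-fold changes, 2360 T. atroviride gene models higher, and 352 T. virens higher and 420 lower. Apart from fewer features tested, the missing normalization and that centring, the cause was not tested. Leaving out 1 array at a time gave 7382 to 9219 features changed, 5534 to 6253 at least 2-fold, 4496 to 5159 higher and 2878 to 4115 lower, 3451 to 3889 T. atroviride gene models higher and 1343 to 1770 lower, and 95 to 188 T. virens higher and 640 to 1171 lower. Low signal limits the dim features, and saturation limits the brightest features on the bright arrays. The folds of dim features may depend on how background is treated, which was not varied alone. The test of feature lists and the averaging of features by annotation were not run.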

Other observations

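Tests on the level dependence and on the correlation of neighbours were chosen only after the result was seen; the tests of runs of neighbouring loci and of other splits of the arrays had their predictions written first.

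In the RMA values, genes that rose strongly lay next to each other more often than chance placement gives. The runs, and the correlations of neighbours given below, were not computed under another normalization. Of the 4572 T. atroviride gene models with a current locus tag, 416 rose at least 4-fold. They formed 11 runs of 3 or more neighbouring loci, at most 2 loci apart with no other matched gene model between. Gene models without a matched locus tag were not placed. The 1000 shuffles within deciles of level gave a median of 2 and a maximum of 8 such runs (permutation p = 0.001, the smallest these shuffles can give). The longest run held 7 gene models over the 8 loci from TrAtP1_005232 to TrAtP1_005239, with log2 fold changes of 2.15 to 4.67. A run of 4 gene models from TrAtP1_002546 to TrAtP1_002550 rose by 3.17 to 6.01, and one of 4 from TrAtP1_011894 to TrAtP1_011899 by 2.25 to 4.87. These runs were picked after their values were seen. The 2 largest rises in the RMA values, TrAtP1_002523 and TrAtP1_002524, are also adjacent. The nearest loci with a matched gene model on either side, TrAtP1_002520 and TrAtP1_002527, had log2 fold changes of -1.81 and -0.20. Loci closer to the pair had no matched gene model, so their change is not known. No excess was detected for falls: the 369 gene models that fell at least 2-fold formed 1 run of 3, where shuffles gave a median of 1 (permutation p = 0.65), and 25 runs of 2 or more, where they gave a median of 18 (permutation p = 0.068). Rises and falls were taken at different sizes, and the difference between them was not tested.

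Neighbouring gene models also changed together: the correlation of log2 fold changes, across gene pairs, was 0.358 for adjacent loci, where shuffles within deciles of level averaged 0.106, and after the level trend was removed it was 0.222, above the highest of 1000 shuffles (0.0682). A shared level alone is therefore argued against as the whole cause. Features that are parts of 1 gene could link adjacent loci, but loci 2 apart still correlated at 0.0954, above the highest shuffle (0.0701), before the value fell to 0.0459 for loci 3 apart and 0.0181 for loci 7 to 10 apart. A small correlation stayed at 11 to 20 loci (0.0211, permutation p = 0.005) and at 50 to 60 loci (0.0171, permutation p = 0.015), which clusters of neighbours do not predict. A candidate explanation of the part at short distance is coregulated gene clusters, a hypothesis found and tested on the same data.

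The rise of nearly all dim T. atroviride gene models after contact may not be a set of separate gene inductions. RNA of the prey carried over with the mycelium is argued against only if it binds probes of both species alike, which was not tested. T. virens gene models of the same level had a median log2 change of -0.136 in the RMA values. With the unnormalized values median-centred it was 0.02, against 0.64 for the T. atroviride gene models. RMA as the whole cause is argued against by the unnormalized values, where the net 5th percentile was at least 1.62 times higher after than before contact within each brightness set. A constant signal added on T. atroviride probes, such as genomic DNA in the labelled material would give, stays open, as does untested low-level transcription of many genes after contact: with levels taken from the bright arrays before contact, the net intensity added on the dim arrays was 61.3 at level 5 to 6 and 137 at level 7 to 8, a ratio of 2.24 where a constant fold would give 3.75, then 157, 150 and 125 in the bands from 8 to 11. The difference turned to -104 at 11 to 12 and -1223 from 14 upward, which an added amount alone cannot give, so other differences between the arrays enter these values, and they rest on 1 dim array before contact; the shape therefore does not decide.

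The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 9552 changed features and 5923 changed at least 2-fold, and 1 of the 10 splits, the real one, reached either count. The highest of the other splits, the one that follows the brightness sets, gave 8 and 8. Every other split mixes the conditions, so the difference between conditions widens the spread within its groups and lowers its counts. These counts therefore do not measure the effect of brightness.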
